A study of Mus musculus with 6 samples.

How the data were processed

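RNA was profiled from crypts of the ileum, the last part of the small intestine, of C57BL/6 mice aged 3 months. Per the labels' protocols, well-oriented crypts were cut from paraffin sections of methacarn-fixed tissue by laser microdissection, RNA was purified with a PicoPure kit, and libraries were made with the Kapa stranded mRNA-seq kit. The 6 libraries fall into 2 genotypes by the genotype label, 3 from wild-type (WT) mice and 3 from Tl1a-transgenic (Tl1a-tg) mice. The labels do not say whether the 3 libraries of a genotype came from separate mice. Any spread between libraries behind the deposited p-values may therefore be technical.

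Per the submitters' processing notes, FastQC, Trimmomatic, Bowtie2 2.1.0, RSEM 1.2.15 and DESeq2 were used by the authors, with no role or order given. The genome build and annotation are not given in the sources used here, so no coordinates are reported. Genes are named as in the deposited tables, and 6797 of the 7120 names were found among current mouse symbols. Another 14 names had been turned into dates by a spreadsheet and were not named here.

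The first deposited table holds signal values per gene and library under a sheet name that calls them normalized counts. The values were checked before any test was chosen. Within a genotype the ratio of any 2 columns was the same for every gene, with a relative range over genes of 1.64e-14 for Tl1a-tg replicates 1 and 2 and of 1.38e-14 for WT replicates 1 and 2. The log2 ratio of the genotypes' mean signal differed from the deposited log2 fold change by a constant of -0.13 over all genes. The deposited signal is therefore 1 fitted mean per gene and genotype multiplied by 1 factor per library, and holds no spread between replicates. The limma test and the camera and fry set tests planned before the data were examined need such a spread and were not run. The only errors that can rest on replicates are the standard errors, Wald statistics (a score) and p-values in the authors' deposited tables. These were used instead.

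The authors' deposited table gives for each gene a mean over libraries, a log2 fold change of Tl1a-tg over WT with its standard error, a Wald score, a p-value and a Benjamini-Hochberg adjusted p-value from DESeq2. The authors gave a p-value for 2580 genes and an adjusted p-value for 1662, and missing values were kept as missing. The deposited values give no reason for a missing p-value, and do not show how many libraries held a gene's reads. Another deposited table gives log2 fold changes shrunken by apeglm with the same p-values. A deposited list that repeats the names of the significant genes was not used. Genes were called at an adjusted p-value below 0.05.

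From the deposited signal, library factors were computed with a geometric mean of 1 over the 6 libraries, and each genotype's fitted mean was divided by them. The resulting depth-adjusted fitted mean is in reads per library at the common depth. Numbers of reads per library were not used here, so the depth is unknown and no counting interval is given. The library factors were 1.01, 1.10 and 0.781 for Tl1a-tg replicates 1 to 3 and 1.34, 0.591 and 1.46 for WT replicates 1 to 3.

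A simulated fit with the smallest mean held at 0.5 gave a genotype without any read a fitted mean of 0.184 and a genotype with 1 read in 1 library 0.358. Fitted means within 1% of 0.184 before scaling to the common depth, and those below 0.01, were taken as genotypes without reads. The former are called the floor below and the latter near 0. This reading is inferred from the values, and a log2 fold change against such a genotype depends on the fitting procedure and is no bound. A gene was called measured in both genotypes with a depth-adjusted fitted mean of at least 10 in each. The dispersion behind each standard error was solved from the fitted means. It lay at a ceiling of 13 for 5405 genes (75.9%). The standard errors of these genes follow from the ceiling and the fitted means, and do not estimate a measured spread between libraries. The ceiling lies above the 10 that the authors' tool sets for up to 10 libraries, so the authors' model may have held libraries beyond these 6. The deposited standard errors and p-values may rest on the spread in those libraries too.

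Before the data were examined, 29 gene lists, the rule for named genes and most alternatives were fixed. Named are Tnfsf15 and its receptor, in each direction the 10 called genes with the smallest p-value and the 10 with the smallest adjusted p-value in the authors' significant table, leaving out clone and predicted-gene names, and from each list the 3 members with the smallest p-value. The 3 Paneth cell products with the highest mean were added. The planned requirement that the 3 values of each genotype lie apart could not be applied to fitted means. The receptor Tnfrsf25 was not analysed here. Any other gene named was chosen after its values were seen.

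For lists with at least 3 measured genes, the median log2 fold change was placed as a percentile among 10000 random lists of the same size, drawn from the measured genes in 10 bins of mean fitted value. Such a percentile describes these genotype values and is not a test over replicates. For each list, p-values were also adjusted over the list alone. Intervals of 95% are Wald intervals from the deposited standard errors.

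The alternatives fixed beforehand were pseudocounts of 0.5 and 5 on the fitted means, other filters, TMM scaling, quantile normalization, an adjusted p-value below 0.1 and the shrunken table. Others were chosen after seeing the data: the floor for all genotypes without reads, p-values for every gene, only genes with reads in both genotypes, centring on the median, a pseudocount of 1, a minimum shrunken size, and list medians over genes with a mean of at least 10 over both genotypes, with near-0 means at the floor. All kept the deposited standard errors. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The adjustment and percentile steps were tested on simulated data. With 7120 simulated p-values, 99.5% of 200 changed genes were recovered, and 4.5% of 200 unchanged lists fell outside the central 95% of random lists. The changed genes were simulated with large scores, so their recovery checks the adjustment step only. It does not measure what the comparison of these genotypes could detect.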

Results

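Ileal crypts hold the stem cells of the epithelium and their neighbours, the Paneth cells, which secrete antimicrobial proteins. The design compares crypts of wild-type mice with crypts of mice that carry a Tl1a transgene. TL1A, encoded by Tnfsf15, is a cytokine of the tumour necrosis factor family, and the series concerns its effect on Paneth cells and ileal inflammation. Each genotype had 3 libraries. The deposited values give 1 fitted mean per gene and genotype, without a value of its own for any library, so the fitted means below carry no SD. The standard errors and p-values are the authors', and may rest on libraries beyond these 6. For 5405 genes (75.9%) the dispersion behind them lay at its ceiling, so these do not estimate a measured spread between libraries. The sums of deposited fitted means, which are not read depths, were 486323, 530625 and 376022 for Tl1a-tg replicates 1 to 3 and 709605, 314186 and 774249 for WT replicates 1 to 3.

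Ribosomal RNA took the largest share of the fitted total in both genotypes, and products of secretory crypt cells led the other genes. The most abundant genes were listed after their values were seen. Rn45s, the ribosomal RNA precursor, took 26.5% of the fitted total in Tl1a-tg and 28.9% in WT. It was followed by Muc2, the main secreted mucin of goblet cells, with fitted means of 12552 and 13390 reads per library. Among Paneth cell products the alpha-defensin Defa24 reached 11784 and 11903, and lysozyme (Lyz1) reached 5207 and 5829. The 20 most abundant genes of each genotype took 48.3% of the fitted total in Tl1a-tg and 50.7% in WT.

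Tnfsf15, the gene of the transgene, had no reads in either genotype by its fitted means, and no fold is given. The authors' deposited table gives it no p-value, and a mean over the libraries of the authors' model of 5.85. A transgene can lack the part of the transcript that is counted, and the labels do not describe the construct, so Tnfsf15 did not serve as a check of the genotype labels. Its receptor Tnfrsf25 was not analysed here.

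The comparison of Tl1a-tg with WT crypts asked which genes differ between the genotypes. The most abundant Paneth and goblet cell products, such as Defa24, Lyz1 and Muc2, had fitted means close to each other in the 2 genotypes, with intervals too wide to exclude several-fold differences in either direction. Other crypt genes had unequal fitted means that did not pass, such as Lgr5 and Ern2, higher in Tl1a-tg, and Xbp1, higher in WT. The genes that passed the authors' test were of another kind, each with no reads in at least 1 genotype. An adjusted p-value below 0.05 was given in the authors' deposited table for 61 genes, of which 41 were higher and 20 lower in Tl1a-tg. All 61 had one genotype fitted near 0, WT for the 41 higher genes and Tl1a-tg for the 20 lower genes, and 1 of the lower genes, Sostdc1 (named after its values were seen), had no reads in either.

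The higher genes were led by Rps16, a protein of the small ribosomal subunit, with a fitted mean of 126 reads per library in Tl1a-tg and none in WT. The authors' deposited table gives it a log2 fold change of 21.77 with a standard error of 3.35 (adjusted p = 1.42e-07 by DESeq2), and a shrunken value of 0.32. Next were Nfia, a transcription factor of the nuclear factor I family, and Nckap1, a subunit of the WAVE complex that drives actin branching, with fitted means of 95.6 and 225 in Tl1a-tg. Mesdc1 (108), Iqsec1 (129), Tmc4 (133), the valyl-tRNA synthetase Vars (114), Dnajc13 (124), the histone gene Hist1h2bj (191) and Tead1 (67.5), a partner of the YAP coactivator, followed with their Tl1a-tg fitted means and no reads in WT.

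The lower genes were led by Naca, a subunit of the nascent polypeptide-associated complex, with a fitted mean of 94.8 in WT and no reads in Tl1a-tg. The authors' deposited table gives Naca a log2 fold change of -22.94 with a standard error of 3.82 (adjusted p = 1.02e-06 by DESeq2). Trim2 (113), the chromatin remodelling subunit Smarcd2 (165), Peak1 (144), the nucleoside transporter Slc28a3 (218), Frmd4b (98.0), Tacc2 (65.1), Prelp (92.8), Cbll1 (144) and Atpif1 (117), an inhibitor of the mitochondrial ATP synthase, followed with their WT fitted means and no reads in Tl1a-tg.

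Over the 61 genes, log2 fold changes in the authors' deposited table were 14.35 to 25.06 in size, and their shrunken values were 0.03 to 0.32. These sizes depended on the value fitted to a genotype without reads. With the near-0 means placed at the floor of the other genes without reads, an alternative chosen after seeing the data, the sizes were 0.13 to 10.53 and 0 of the 61 genes passed, the smallest adjusted p being 0.248. At an unadjusted Wald p below 0.05, 40 of the 61 remained, and 334 genes in all had such a p under this setting. The 61 were chosen by their p-values in these same data, so the 40 are no independent support.

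**Figure D1:**
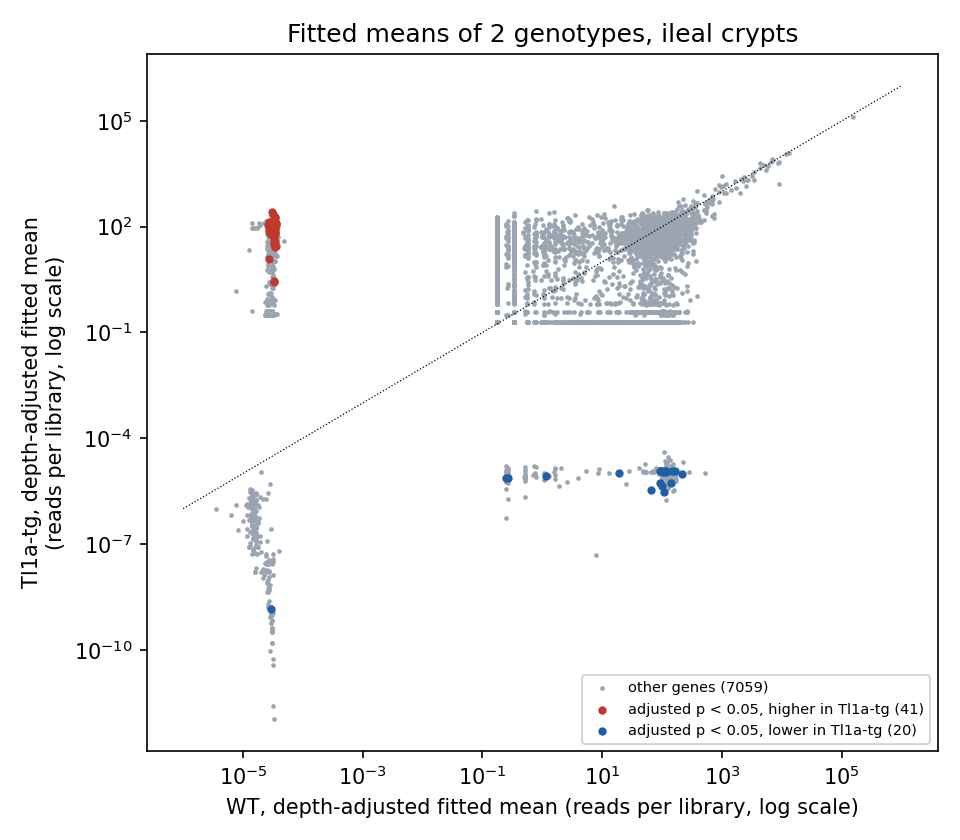
Depth-adjusted fitted mean of each of the 7120 listed genes in WT (horizontal) and Tl1a-tg (vertical), in reads per library on log axes, with the line of equality dotted. The 61 genes at an adjusted p below 0.05 in the authors' deposited table (41 red, 20 blue) lie in the bands near 0, which hold genotypes without reads.

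Genes with reads in both genotypes did not pass. There were 2446 such genes, and the authors' deposited table gives a p-value for 1305 of them. The smallest adjusted p was 0.0727 for Ctnnb1, which encodes beta-catenin of the Wnt pathway, with fitted means of 240 in Tl1a-tg and 0.342 in WT (named after its values were seen). An unadjusted DESeq2 p below 0.05 was given in the authors' deposited table for 88 of these genes, 65 higher and 23 lower. Of the 88, 0 passed after adjustment, and none was measured in both genotypes. Of the 828 genes measured in both genotypes with a deposited p-value, 0 had an unadjusted DESeq2 p below 0.05, the smallest being 0.103. The WT mean of Ctnnb1 lay near the 0.358 that the simulated fit gave, before scaling, to 1 read in 1 library. For the 1379 genes measured in both genotypes, the median standard error in the authors' deposited table was 3.93 on the log2 scale. The smallest standard error of any gene, 1.80, gives a 95% half-width of 3.53, or 11.6-fold, so smaller differences were not detectable.

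The abundant members of the design's central group, the Paneth cell antimicrobial products, had fitted means within about the same range in both genotypes. Of 34 genes in the list 17 were listed and 16 measured in both genotypes, 6 with a positive and 10 with a negative log2 fold change, and 0 passed, over all genes or adjusted over the list alone. Defa2 had fitted means of 7057 in Tl1a-tg and 9132 in WT, Defa17 8263 and 6962, Defa20 6491 and 4361, the lectin Itln1 3983 and 5420, and the secreted phospholipase Pla2g2a 221 and 391. In the authors' deposited table the log2 fold change was -0.01 for Defa24 (95% interval -3.94 to 3.91), -0.16 for Lyz1 (-4.14 to 3.82) and -0.82 for Pla2g2a (-5.57 to 3.92). Defa25, named after its values were seen, was left out by the measured limit, with no reads in Tl1a-tg and 25.3 in WT. Its log2 fold change was -7.04 with a standard error of 4.41 in the authors' deposited table, without a p-value. Alpha-defensin genes are near-identical copies whose reads can be split between them, so their values are uncertain one by one. The median of the list was -0.16, at the 63.0th percentile of random lists, and stayed at -0.16 over the 17 genes chosen by their mean over both genotypes, 6 positive and 11 negative. Its sign turned to 0.22 when the median log2 fold change of all measured genes, -0.38, was set to 0.

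Paneth cell regulators and surface genes had a median log2 fold change of -0.77 over 8 measured genes, 2 positive and 6 negative, at the 9.07th percentile, and 0 passed. Xbp1, a transcription factor of the unfolded protein response, had fitted means of 0.311 in Tl1a-tg and 97.0 in WT, and the authors' deposited table gives p = 0.0603 and an adjusted DESeq2 p of 0.247. Nupr1 had 237 and 33.5 and Habp2 had 101 and 344. The matrix metalloproteinase Mmp7, which processes alpha-defensins, had 437 and 693, and was named after its values were seen.

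Goblet cell genes had a median of 0.16 over 8 measured genes, at the 90.6th percentile, with 0 passing. It was 0.75 over 12 genes chosen by their mean over both genotypes, 9 positive and 3 negative. This lay at the 97.7th percentile and so outside the central 95% of random lists. Over all 4538 genes chosen by that mean the median was 0.68, close to 0.75. Those genes were not matched to the list by their mean, whereas the random lists were, with a central 95% of -1.53 to 0.727. Beyond Muc2, the authors' deposited table gives p = 0.0137 for Ern2, an endoplasmic reticulum stress sensor of mucous cells (fitted means 282 in Tl1a-tg and 0.774 in WT), and p = 0.0226 for Agr2, a disulphide isomerase needed for mucin (186 and no reads). Both had an adjusted DESeq2 p of 0.23. Creb3l1 had 248 and 106. Stem cell genes had a median of 0.07 over 7 measured genes, at the 81.1th percentile, with 0 passing, and of 0.41 over 13 genes chosen by that mean, 8 positive and 5 negative (80.7th percentile). Lgr5, the receptor that marks crypt base stem cells, had fitted means of 131 in Tl1a-tg and 0.342 in WT. In the authors' deposited table its log2 fold change was 8.59 with a standard error of 3.68 (p = 0.0198, adjusted p = 0.23 by DESeq2). Znrf3 had 120 and 1.29 and Prom1 had 64.2 and no reads, with the same adjusted p of 0.23 in the authors' deposited table. In the other direction, Cdca7 had no reads in Tl1a-tg and 90.3 in WT, and Lrig1 had none and 27.0 (both named after their values were seen). Of the list, 2 genes were read in Tl1a-tg only and 2 in WT only. Olfm4, another stem cell gene, named after its values were seen, had 677 and 679.

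**Figure D2:**
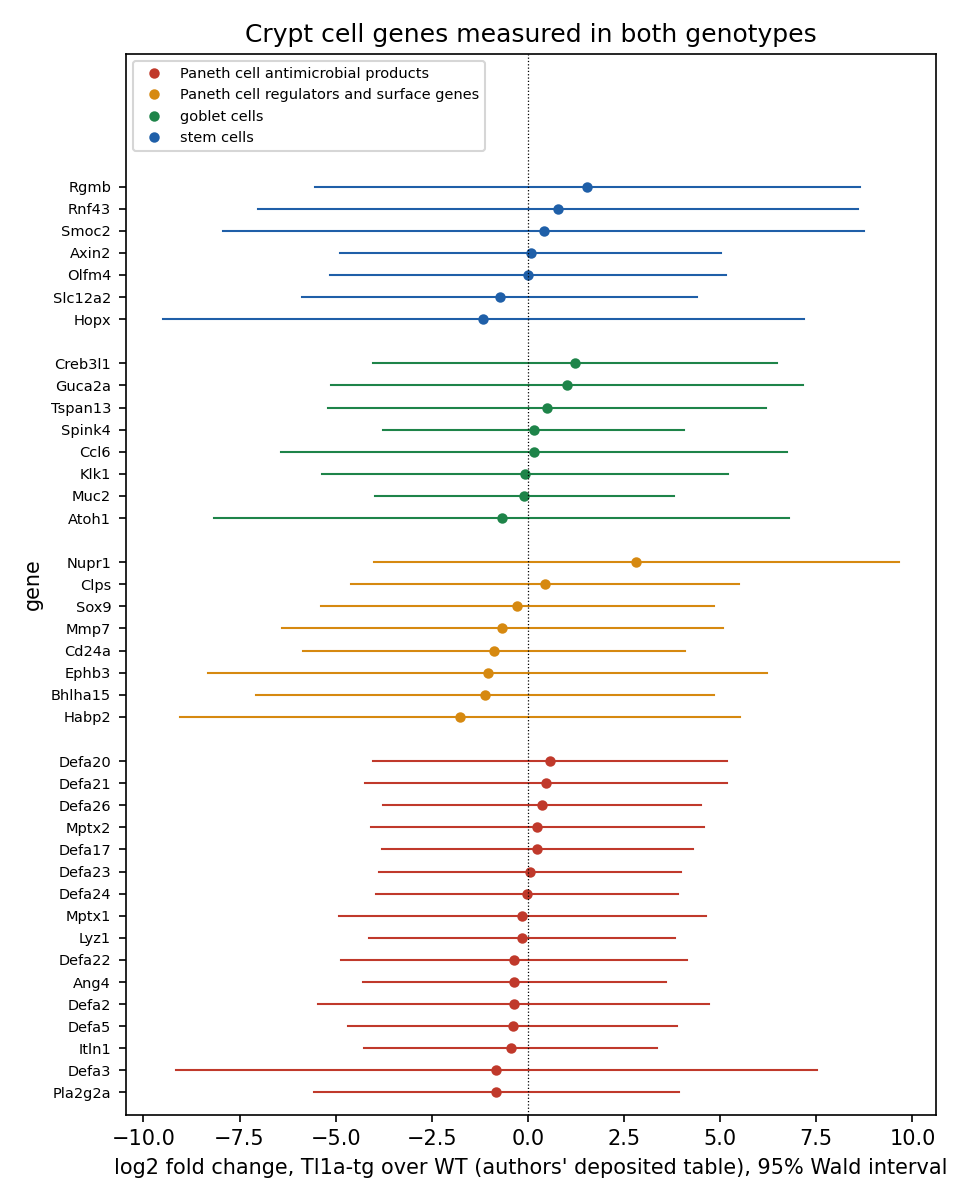
Log2 fold change of Tl1a-tg over WT (horizontal, points) with 95% Wald intervals (lines) from the authors' deposited table, for genes of 4 crypt cell lists measured in both genotypes (vertical). Every interval includes 0.

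Genes of defence and inflammation were thinly measured. Inducible epithelial defence genes had a median of 0.30 over 4 measured genes (88.6th percentile), and of 0.50 over 8 genes chosen by their mean over both genotypes (77.4th). Among them Reg3g, an antibacterial lectin named after its values were seen, had 357 and 360. Sprr2a1, whose values equal those of its near copy Sprr2a2, had 155 and 109, and both copies are counted in these medians. Tgm2 had 30.7 and 0.342, and Lypd8 had 5.82 in Tl1a-tg and 197 in WT. Duox2 had 82.0 in Tl1a-tg and 0.266 in WT, and Duoxa2 had 36.0 and no reads. Both were named after their values were seen and had no p-value in the authors' deposited table. Of the 8 genes, 6 had a positive and 2 a negative log2 fold change. Antigen presentation and interferon gamma genes had a median of 0.19 over 3 measured genes (80.01th percentile), while their mean of -0.39 had the opposite sign, as had the median of -4.67 over 10 genes chosen by that mean. Cd74, the invariant chain of class II molecules, had 0.621 and 76.0, H2-K1 had 130 and 63.4, and H2-D1 had no reads in Tl1a-tg and 0.577 in WT. Type 2 cytokine response genes had a median of 0.51 over 6 measured genes (95.4th percentile), which became -0.29 when a mean of at least 50 was required, and 0.99 over 10 genes chosen by their mean over both genotypes (85.4th percentile). Il13ra1 had 71.7 and no reads, Pla2g4c 57.7 and 227, and Muc13 529 and 322. Of the NF-kB and tumour necrosis factor family list, Cxcl16 and Tnfrsf1b had no reads in either genotype. Lif had 34.7 in Tl1a-tg and 13.5 in WT, and Cxcl5 had no reads in Tl1a-tg and 62.0 in WT (both named after their values were seen). The type I interferon list had no measured gene and no deposited p-value. No gene of these 5 lists passed.

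Endoplasmic reticulum stress genes had a median of -1.03 over 9 measured genes, 3 positive and 6 negative (11.4th percentile). It turned to 0.63 over 17 genes chosen by their mean over both genotypes, at the 77.4th percentile of random lists matched by mean. The unmatched median over all genes chosen so was 0.68. Pdia3 had 166 and 0.789, Dnajc3 had no reads in Tl1a-tg and 65.9 in WT, and Hsp90b1 had 19.1 and no reads in WT. Cell cycle genes had a median of -1.14 over 3 measured genes (22.9th percentile), which turned to 7.14 over 9 genes chosen by that mean. The proliferation marker Mki67 had 145 and 88.1, Hmgb2 46.9 and 104, and Stmn1 2.19 and 0.342. Of the autophagy list, Sqstm1 had 112 and 36.1, Ulk1 112 and 145, and Wipi2 3.82 and 17.6. No gene of these 3 lists passed. The cell death list held the 1 called gene among the 29 lists, over all genes and adjusted over the list alone. Bak1, a pore-forming protein of the mitochondrial apoptosis pathway, had a fitted mean of 54.2 in Tl1a-tg and none in WT. The authors' deposited table gives it a log2 fold change of 20.63 with a standard error of 4.38 (adjusted p = 7.96e-05 by DESeq2), a call that was lost with the near-0 mean at the floor. Casp8 had no reads in Tl1a-tg and 90.4 in WT (adjusted p = 0.23 in the authors' deposited table, by DESeq2), and Bcl2l1 had 0.375 and 0.342.

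Several markers of other cell types were read in one genotype only. The T cell gene Cd8b1 had 128 in WT and no reads in Tl1a-tg, and the tuft cell gene Trpm5 had 98.6 in WT and no reads in Tl1a-tg. Both were named after their values were seen and had no p-value in the authors' deposited table. How many WT libraries held these reads is not known. Of the absorptive enterocyte list, Vil1 had 138 in Tl1a-tg and 12.6 in WT, Anpep 79.98 and 45.0, and Slc10a2 1.57 and 0.342. The enteroendocrine gene Gcg had 28.7 and 62.7, and the tuft cell genes Dclk1 and Cd300lf had 19.4 and 98.0, and 4.69 and 15.1. Of myeloid genes, Kit had 175 and 363, Cx3cr1 11 and 2.43, and Lyz2 no reads in Tl1a-tg and 0.544 in WT. Fibroblast genes Fn1 and Vim had 133 and 50.5, and 7.08 and 4.06. The B cell gene Cd22 had 3.04 and 0.939, the neuronal gene Tubb3 no reads and 1.02, and Clps, listed under exocrine pancreas and Paneth cells, 1615 and 1183. Lists of T and innate lymphoid cells and of smooth muscle had no gene measured in both genotypes and no deposited p-value, and no gene of the endothelial or mitochondrially encoded lists was analysed here. No gene of these lists passed.

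Among metabolic and stress response lists, Hadhb, of mitochondrial fatty acid oxidation, had no reads in Tl1a-tg and 138 in WT, and Sqle, of cholesterol synthesis, had none and 76.0. Acot2 had 3.31 and 0.561, Ppargc1a 30.7 and 95.2, and Srebf2 214 and 58.2. Zfp36, an immediate early gene, had 143 in Tl1a-tg and none in WT, Dnajb1 16 and none, and Jun 3.94 and 22.0. Of the circadian clock list, Nr1d2 had 30.4 and none, Clock 0.950 and none, and Cry2 0.668 and 11.4. In the authors' deposited table the p-values of Hadhb, Sqle and Zfp36 were 0.0315, 0.0489 and 0.0282, with adjusted DESeq2 p of 0.23 for each, and no gene of these lists passed. Of the 9 lists with 3 or more measured genes, 0 had a median outside the central 95% of random lists. Requiring a fitted mean of at least 10 in each genotype leaves out the most unequal genes. Over all 4538 genes chosen by their mean over both genotypes, the median log2 fold change was 0.68. With list genes chosen so, after seeing the data, 3 of 20 lists had a median outside the central 95%. They were goblet cells (0.75, 97.7th percentile), antigen presentation (1.38th) and cholesterol synthesis (98.1th). Lists drawn at random fall outside for about 5%, and these percentiles are no test over replicates.

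The genotypes also differed in how many genes had no reads. Of the 7120 listed genes, 3510 (49.3%) had none in WT and 2438 (34.2%) had none in Tl1a-tg. Reads were present in Tl1a-tg only for 2236 genes and in WT only for 1164, and 1274 genes had none in either genotype. This surplus had no replicate check.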

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

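In this part, the tests of expression level and of sparse reads were planned before their results were seen, and the tests of the floor, of library factors, of the share of abundant genes and of the mean over libraries were chosen only after the result was seen.

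The mean over libraries in the authors' deposited table, which the comparison did not use, was above 3 for 501 genes that had no reads in either genotype by their fitted means, a signal in values outside the main measurement, with a median of 2.57 over all 1274 such genes and a highest value of 861, for Fnip2; Tnfsf15 was among the 501, with 5.85. A mean taken over the 6 libraries alone would be nearly proportional to the summed fitted means, yet over genes measured in both genotypes the 95th percentile of that ratio was 14.7 times the 5th, which argues against it. A candidate explanation is that the authors' model held further libraries. The dispersions solved from the standard errors stopped at 13 for 5405 genes (75.9%), where the tool's usual ceiling is 10 for up to 10 libraries and the number of libraries above that. Under that rule a ceiling of 13 would match a model of 13 libraries. The column labels call the 6 libraries young and name no others. What those libraries were and any biological explanation were not tested. For genes below the ceiling, the deposited standard errors and p-values would then rest on the spread in those libraries too.

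All 61 genes called in the authors' deposited table had one genotype fitted near 0. With these means at the floor of the other genes without reads, 0 calls were left: log2 sizes went from between 14.35 and 25.06 to between 0.13 and 10.53 at unchanged standard errors (median 4.41), so the calls ended because the fold became smaller. A called gene had the higher fitted mean than an uncalled gene with reads in one genotype with a probability of 0.774 (bootstrap 95% interval 0.706 to 0.830). Stronger expression may therefore contribute. Yet among tested genes with reads in one genotype only, 60 of 61 with a near-0 mean were called, and 0 of 828 at the floor. Of those at the floor, 113 had at least the called genes' median of 92.5. These values argue against stronger expression alone as what set the calls apart. Chance absence of reads at the fitted dispersion gave 75.5% of the observed number of tested genes with reads in one genotype only (671 of 889), between the bounds set beforehand, which leaves it open. A genotype effect on single called genes stays open and untested, and 3 of the calls (Cotl1, Sbno1 and Sostdc1, named after their values were seen) had a fitted mean below 1 in both genotypes.

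More genes lacked reads in WT (3510) than in Tl1a-tg (2438). A lower depth of the WT libraries stays open: their library factors had a geometric mean 1.10 times that of Tl1a-tg, and the ratio of the sums of deposited fitted means was 1.29, both against it. The factor ratio stayed above 1 without WT replicate 2 (1.46) or Tl1a-tg replicates 1 (1.13) and 2 (1.18), but fell to 0.973 without WT replicate 1, 0.931 without WT replicate 3 and 0.993 without Tl1a-tg replicate 3. A few genes taking up WT reads was argued against, as the 20 most abundant genes of each genotype took 2.35 percentage points more of the fitted total in WT. Lower RNA complexity of the WT captures and a genotype effect were not tested and stay open.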

How the results depend on the processing

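The alternatives with near-0 means at the floor, with p-values for every gene, with only genes read in both genotypes, with centring, with list genes chosen by mean, with a pseudocount of 1 and with a minimum shrunken size were chosen after seeing the data. The 61 calls stayed under TMM scaling (61 shared, shift -0.07), without a filter (60 shared) and with median centring (61 calls, 60 shared, shift -0.38). At an adjusted p below 0.1 there were 64 calls, and the shrunken table lists the same 61. Both shifts are small beside log2 sizes of 14.35 or more, and the shrunken table repeats the deposited p-values. Scaling, centring and the shrunken table could therefore hardly change the calls. Requiring a mean of at least 50 left 23 calls, 14 higher and 9 lower, as fewer genes were tested. Pseudocounts of 0.5, 1 and 5, quantile normalization, the floor and the restriction to genes with reads in both genotypes each gave 0 calls, with smallest adjusted p of 0.543, 0.735, 1, 1, 0.248 and 0.683. The first 5 of these shrink the fold against a genotype without reads, and the last leaves such genes out. The highest fitted mean among the calls was 260, and their standard errors stayed as deposited (median 4.41). Loss of the 61 calls was thus nearly fixed in advance, and does not by itself weigh against a genotype effect on single genes. A shrunken log2 fold change of at least 1 was met by 0 of the 61. P-values for every gene gave 551 calls, 276 higher and 275 lower, of which 487 had no deposited p-value. The 1 list with a call fell to 0 under the pseudocounts, quantile normalization and the floor, and became 14 with p-values for every gene. All 21 called named genes lost the call under the pseudocounts, quantile normalization and the floor, and no uncalled gene named by the rule gained one under any alternative. Of genes named outside the rule, Ctnnb1 passed at an adjusted p below 0.1 (0.0727), and Ctnnb1, Cdca7, Cd8b1 and Trpm5 passed with p-values for every gene. Cdca7, Cd8b1 and Trpm5 had no deposited p-value, and whether their reads came from 1 library is not known.

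No alternative bears on whether Tnfsf15 had reads. Among uncalled genes named by the rule, the sign turned for 1 under TMM scaling (Defa24, 0.06), 4 under quantile normalization (Stmn1, Slc10a2, Cd22 and Vim) and 3 under median centring (Ulk1, Defa24 and Defa2). The sign of a list median turned for type 2 cytokine response (-0.29 with a mean of at least 50) and Paneth cell antimicrobial products (0.22 with median centring). Over genes chosen by their mean over both genotypes it turned for antigen presentation (-4.67), endoplasmic reticulum stress (0.63) and cell cycle (7.14). The median over all genes chosen by that mean was 0.68, against -0.38 over the genes measured in both genotypes. Array weights, the untrended fit, count models on recovered reads, camera, fry, the fits without each replicate, the permutation test of Tnfsf15 and other splits of the 6 libraries were not run, because the fitted means hold no value per library. No paired analysis was possible because the columns of a genotype differ only by a constant factor. The unknown depth and the dispersions, 2.34 at the least, limit what was detectable.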

Other observations

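In this part, the test on ribosomal protein genes was planned before its result was seen, and the counts by list were made only after the genome-wide surplus was seen.

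Of the 76 ribosomal protein genes listed, a group chosen after Rps16 led the called genes, 58 had reads in both genotypes, 14 in Tl1a-tg only and 2 in WT only. Of the 54 with a p-value in the authors' deposited table, 9 had an unadjusted DESeq2 p below 0.05, each higher in Tl1a-tg, and 1 (Rps16) passed after adjustment. Over all genes in the authors' deposited table, 376 of 2580 had such a p, 275 of them higher. Rpl29 had fitted means of 87.9 in Tl1a-tg and 0.342 in WT, Rpl23a 77.8 and 0.581, and Rps6 70.8 and no reads in WT. In the other direction Rps14 had 1.08 and 133, Rps20 0.375 and 86.8, and Rpl8 3.08 and 104. Over the 35 measured in both genotypes the median log2 fold change was 0.08. One hypothesis is that these genes follow the general surplus of genes without reads in WT. Of the 16 read in one genotype only, 87.5% were read in Tl1a-tg only, on the upper limit of the central 95% of matched random sets (37.5% to 87.5%), so they may follow that surplus, and an effect of their own was not excluded.

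Some fixed lists leaned the same way as the 65.8% of all one-genotype genes that were read in Tl1a-tg only. Of circadian clock genes 7 were read in Tl1a-tg only and 0 in WT only, among them Per1 (fitted mean 23.6), Per3 (24.2) and Npas2 (30.3), while Per2 had 0.375 in Tl1a-tg and 54.2 in WT. Of cholesterol synthesis genes, Dhcr7 (54.2) and Hmgcs1 (31.5) were read in Tl1a-tg only and Sqle (76.0) in WT only. Immediate early and heat shock genes numbered 6 and 2, with Klf2 (76.9) and Atf3 (45.5) in Tl1a-tg only and Fos (73.9) in WT only. Antigen presentation genes numbered 2 and 5. None of these splits was tested. Xkrx, the gene with the most unequal fitted means among the 20 most abundant, had 1584 in Tl1a-tg and 9031 in WT, and the authors' deposited table gives it a log2 fold change of -2.51 with a standard error of 2.44.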
